A study of Oryza sativa with 6 samples.

How the data were processed

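RNA from 7-day-old light-grown rice seedlings was hybridised to Affymetrix rice arrays with a biotin label, 1 array per sample, per the labels. The groups were a solvent control, IAA and BAP, taken from the sample titles, with 2 arrays each. The series design calls the replicates biological. The deposited value table gives 1 intensity per probe set and array on a linear scale, with scanner software, background correction and summary method not given in the sources used here. The trimmed means of the deposited intensity differed between arrays, from 147 to 182, so the values had not been scaled to a common trimmed mean. No detection calls were used. The experiment files of the scanner software were used only for run day and fluidics module, per the file headers. Control arrays occupied modules 1 and 2, IAA arrays modules 3 and 4 on the same day, and BAP arrays modules 3 and 4 on another day.

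The table held 57381 probe sets, of which 187 were array controls and were left out. Values were taken as log2(intensity + 16), which understates the change of dim genes. The array medians on this scale differed by up to 0.262, above the limit of 0.1 set before the data were examined, so the arrays were quantile normalized. Target probe sets whose mean log2 value lay under the 40th percentile (4.70, near an intensity of 9.94) were left out, which removed 22878 and kept 34316. Intensities printed for single genes are normalized values with the 16 subtracted again, as means ± SD of 2 arrays.

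Group means were fitted with limma 3.58.1 in R 4.3.3 over all 6 arrays, with 3 residual degrees of freedom and an empirical Bayes spread that followed intensity (median prior degrees of freedom 6.07). Contrasts were IAA against control, BAP against control and BAP against IAA. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the tested probe sets. Every adjusted p of a gene is two-sided and from limma. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used to read the tables and draw the plots.

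Probe sets were named through the platform annotation table, matched by gene number to a RefSeq gene table of a japonica assembly. That table served for names and for the order of neighbouring genes, since the samples are of the indica subspecies. It named 22436 probe sets with 1 gene and 95 with several, from which no name was taken, and left 34663 unnamed here. The named probe sets stood for 17905 genes, of which 2444 carried a symbol other than a locus number. Probes of near-identical copies, such as RR9 and members of the OPR, glutathione S-transferase and Aux/IAA families, can share signal, so the values of single copies are uncertain.

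The rule for named genes was set before the data were examined. It took the 10 largest increases and the 10 largest decreases against the control, and the 5 each way between hormones, among probe sets past the threshold with 1 named gene and with every array of one group on the same side of every array of the other. Where fewer passed, those were named. Up to 4 members of each gene list with the smallest p were added. The tables gave no product descriptions, so a gene counted as named where it carried a symbol, and list membership rested on symbols and synonyms in place of descriptions. The list of root-preferential genes consisted mostly of CASP-like genes as a result, and their preference for root was not examined. The list of cytokinin synthesis and activation consisted only of LOG genes, which act in activation.

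The 28 gene lists were fixed before the data were examined, and 23 held at least 3 measured genes. They were tested with camera at an inter-gene correlation of 0.01 over 16464 genes, with the brightest probe set standing for each gene, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way and does not compare them with other genes. Adjusted p-values cover the 23 lists of a comparison. With an estimated correlation 0 lists passed in any comparison (5, 3 and 5 at an unadjusted p under 0.05 for IAA, BAP and their difference). That version rests on the 3 residual degrees of freedom and has little power, so a failure in it does not show that correlation explains a list. The estimated correlation was -0.0117 for GH3 genes and -0.107 for glutathione S-transferases, below the preset 0.01. For other lists it was higher, up to 0.438 for cytokinin dehydrogenases. With fry, Aux/IAA, GH3, ethylene synthesis and glutathione S-transferase genes passed for IAA, and type-A response regulators, cytokinin dehydrogenases and expansins for BAP.

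The fit was tested on simulated data with 200 changed probe sets among 34316 in the comparison of IAA with control. It recovered 7 of 61 with a log2 change of 0.5, 42 of 70 with a change of 1 and 68 of 69 with a change of 2, and called 12 of 34116 unchanged ones. In the comparison of BAP with control, simulated with no change, 2 probe sets were called. The list test recovered 5 of 5 changed lists of 8 genes and called 0 of 5 unchanged ones. Genes were simulated as independent and all genes of a changed list moved by 0.5 one way. False calls from correlation between genes were therefore not tested. Simulated unchanged groups with shared controls gave the reference values for both hormones, with lists as long as the called ones for the overlaps.

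Array controls were examined for a shift between run days. None of the 187 was past the threshold in limma in any comparison, with lowest adjusted p of 0.163 for IAA, 0.225 for BAP and 0.147 between hormones, and 9, 12 and 9 had an unadjusted p under 0.05. Their fit used deposited values and a spread that did not follow intensity. For target probe sets that spread left 13 calls with BAP in place of 94, so the test had little power and a shift is not excluded. The comparison of IAA with control holds no difference in run day. Alternatives covered the filter, the scaling between arrays, the pseudocount, a floor, the spread model, the arrays in the fit, a replicate block, the threshold, a plain test and each array left out.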

Results

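Gene expression was measured in light-grown seedlings of the indica rice variety IR64 at 7 days of age, after treatment with an auxin, a cytokinin or the solvent alone. The auxin was indole-3-acetic acid (IAA, 50 µM) and the cytokinin was benzyl aminopurine (BAP, 50 µM). Control seedlings received 0.1% dimethyl sulfoxide. Tissue taken after 1 h and 3 h was pooled in equal parts for each sample, so early and later responses were not separated. Each group held 2 biological replicates, according to the series design, and each replicate was hybridised to its own Affymetrix rice array. The 6 arrays carried 57381 probe sets, of which 34316 target probe sets were bright enough to be tested. The median deposited intensity ranged from 16.6 to 23.1 between arrays. Replicates correlated across probe sets at r = 0.988 in the control, 0.983 in the IAA group and 0.983 in the BAP group, where probe sets are not independent replicates. BAP array 1 correlated more closely with the control arrays (r = 0.985 and 0.984) than with BAP array 2. In a principal component analysis, BAP array 2 stood apart on the second component (21.4% of the variance), at -40.1 against 4.14 for BAP array 1. The small number of arrays limits the precision of every value. Control and IAA arrays were run on the same day, whereas both BAP arrays were run on another day. No control or IAA array was run on that day, so the effect of BAP and the effect of run day cannot be told apart. Control arrays used fluidics modules 1 and 2, and IAA and BAP arrays modules 3 and 4. Module therefore cannot be told apart from IAA or from BAP in the comparisons with control.

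The first comparison asked which genes IAA changed against the control. IAA raised genes of the early auxin response, led by Aux/IAA genes, which encode repressors of auxin signalling, and GH3 genes, which encode enzymes that join amino acids to auxin or related acids. IAA20 (LOC4340245) rose from an intensity of 196 ± 9.73 in the control to 2624 ± 197 with IAA (SD, n = 2 arrays each), and IAA9 (LOC4331061) rose from 226 ± 23.2 to 2758 ± 27.5. GH3-2 (LOC4326893) rose from 839 ± 36.5 to 5171 ± 259. Fewer genes fell, and the named gene with the steepest fall was VIT1.2 (LOC4346978), a vacuolar iron transporter gene, which went from 422 ± 10.3 to 108 ± 6.14.

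In limma, 292 probe sets differed between IAA and control, of which 217 were higher and 75 lower with IAA. At least 2-fold changes made up 154 of the higher and 41 of the lower probe sets. The called probe sets with a single gene stood for 194 genes, 60 of which carried a name. Without rescaling the deposited values between arrays, 244 were higher and 258 lower, so the excess of increases did not hold under that scaling. The median log2 change over all tested probe sets was then -0.0848, against -0.00749 after quantile normalization. With each array centred on its median, 171 were higher and 50 lower. The count was 85 without control array 1, 149 without control array 2, 103 without IAA array 1 and 178 without IAA array 2, and it was 68 with dim probe sets kept, 92 with a spread that did not follow intensity and 0 in a plain two-group test per probe set (3055 at an unadjusted p under 0.05, against 3723 in limma).

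**Figure D1:**
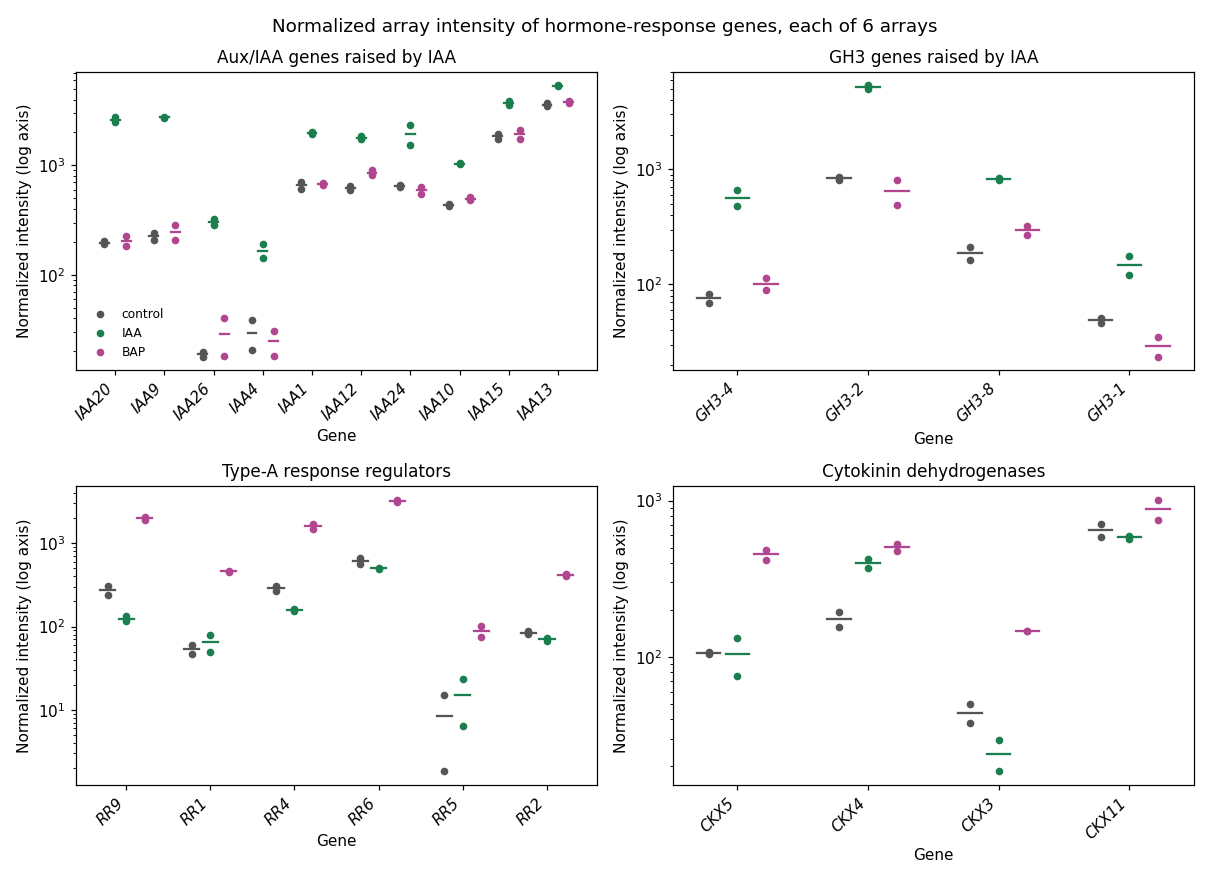
Normalized intensity on a log axis of Aux/IAA and GH3 genes raised by IAA, and of all measured type-A response regulator and cytokinin dehydrogenase genes. Points are single arrays (grey control, green IAA, purple BAP) and horizontal lines are group means; RR6, for example, had means of 609 in the control, 499 with IAA and 3213 with BAP.

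By the rule for named genes, all 20 genes in this paragraph had both IAA arrays on one side of both control arrays. On the log2 scale, IAA20 rose by 3.64 (SE 0.14, limma adjusted p = 2.32e-05), IAA9 by 3.52 (SE 0.16, adjusted p = 2.40e-05) and IAA26 by 3.21 (SE 0.24, adjusted p = 0.000529). Next came BHLH172, a helix-loop-helix protein gene also known as BU1, at 2.99 (SE 0.24), GH3-4 at 2.66 (SE 0.19) and GH3-2 at 2.60 (SE 0.19). WOX6, a WUSCHEL-related homeobox gene, rose by 2.35 (SE 0.22), the glutathione S-transferase gene GSTU1 by 2.23 (SE 0.19), GH3-8 by 2.06 (SE 0.15) and OPR4, of the 12-oxophytodienoate reductase family, by 2.05 (SE 0.13), with limma adjusted p between 0.000195 and 0.00171 for these 7 genes. VIT1.2 changed by -1.82 (SE 0.14, limma adjusted p = 0.000529) and the helix-loop-helix protein gene ILI6 by -1.35 (SE 0.16, adjusted p = 0.00555). The peroxidase genes PRX112 and PRX74 changed by -1.15 (SE 0.14) and -0.87 (SE 0.13), the glyceraldehyde-3-phosphate dehydrogenase gene GAPC2 by -1.04 (SE 0.18) and the type-A response regulator gene RR9 by -1.03 (SE 0.15). BGLU26, a beta-glucosidase gene, changed by -0.91 (SE 0.14), the splicing factor gene RSZ21a by -0.88 (SE 0.11), the aluminium transporter gene Nrat1 by -0.85 (SE 0.15) and the acyltransferase gene AT4 by -0.83 (SE 0.12). A second probe set of PRX112 read -0.02 and 2 other ones of RSZ21a read 0.10 and -0.45 (limma adjusted p = 0.85 and 0.291), so these genes were not uniform across their probe sets. The 10 increases and the fall of VIT1.2 stayed past the threshold with each array left out, whereas each of the other 9 decreases lost its call without any of at least 2 arrays, a control array among them, with adjusted p up to 0.287 for GAPC2 and Nrat1 without control array 1.

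Among the gene lists fixed before the data were examined, the Aux/IAA, GH3 and auxin response factor lists ranked above other genes with IAA in camera at its preset correlation. None of the 3 passed with an estimated correlation, a version with 3 residual degrees of freedom and little power. In fry the first 2 passed and the auxin response factors did not (adjusted p = 0.0638). Of 25 measured Aux/IAA genes, 10 rose and 0 fell in the test over all probe sets, and adjusted over the list alone 15 rose and 1 fell. Beside the genes above, IAA1 rose by 1.56 (SE 0.11) and IAA12 by 1.51 (SE 0.11), both with a limma adjusted p of 0.000529. A second, dimmer probe set of IAA1 read 0.13 (limma adjusted p = 0.911). The list ranked above other genes in camera at an adjusted p of 1.79e-16, and at adjusted p = 0.108 with an estimated correlation. Of 9 GH3 genes, 4 rose and 0 fell, and the same numbers held adjusted over the list alone (camera adjusted p = 3.43e-06, and adjusted p = 0.125 with an estimated correlation). GH3-1 was the fourth, at 1.32 (SE 0.22, limma adjusted p = 0.0329), and lost its call without any control or IAA array (adjusted p up to 0.209). Among 16 auxin response factor genes, which encode the transcription factors that Aux/IAA proteins restrain, ARF10 rose by 1.21 (SE 0.14, limma adjusted p = 0.00583) and ARF23 by 0.78 (SE 0.12, adjusted p = 0.0238). Adjusted over the list alone, 5 of them rose and 0 fell, with a camera adjusted p of 7.58e-05 and adjusted p = 0.29 with an estimated correlation. ARF10 and ARF23 lost their calls without control array 1 (adjusted p = 0.0852 and 0.213) or IAA array 1, and ARF23 also without control array 2. The 4 auxin carrier genes held 0 calls, and 1 rose adjusted over the list alone, PIN3A at 0.45 (SE 0.13).

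Other lists also ranked above other genes with IAA in camera at its preset correlation, and none with an estimated one. In fry, glutathione S-transferases and ethylene synthesis passed among them. Of 6 glutathione S-transferase genes, 3 rose, also adjusted over the list alone: GSTU1, GSTU6 at 1.68 (SE 0.15) and GSTZ5 at 0.79 (SE 0.14), the last of which lost its call with any array left out (camera adjusted p = 1.35e-05, and adjusted p = 0.125 with an estimated correlation). Among 8 cytokinin activation genes, all of the LOG family, LOGL3 rose by 1.80 (SE 0.22, limma adjusted p = 0.00655). Adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 0.00375, and adjusted p = 0.227 with an estimated correlation). Genes of the other steps of cytokinin synthesis were not in the list. LOGL3 had adjusted p up to 0.0808 when dim probe sets were kept or the spread did not follow intensity. Among the 3 genes of ethylene synthesis, ACS1 rose by 1.69 (SE 0.26, limma adjusted p = 0.0203), also adjusted over the list alone. Its control arrays were close to background, its log2 change ranged from 0.68 with a pseudocount of 64 to 4.04 with one of 1, and its call was lost without any of the control or IAA arrays (adjusted p up to 0.153). The list had a camera adjusted p of 0.0423, adjusted p = 0.29 with an estimated correlation, and 0.118 without IAA array 1; it also missed the threshold without control array 2, IAA array 2 or either BAP array. The list of 15 TIFY genes held jasmonate repressor (JAZ) genes and also TIFY1A, TIFY2A and TIFY2B, which carry GATA synonyms and no JAZ synonym. Among the 15, TIFY11B rose by 0.88 (SE 0.14, limma adjusted p = 0.0254), and adjusted over the list alone 4 rose and 0 fell. The TIFY list had a camera adjusted p of 0.0105, adjusted p = 0.303 with an estimated correlation, and 0.372 without IAA array 1, and TIFY11B itself lost its call without any control or IAA array (adjusted p up to 0.202). The 6 clock genes held 0 calls, also adjusted over the list alone, although all 6 log2 values were above 0 (camera adjusted p = 0.0322, adjusted p = 0.303 with an estimated correlation, 0.101 without control array 2 and 0.264 without IAA array 1).

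Type-A response regulators, heat shock proteins, and cyclins with histones ranked below other genes with IAA in camera at its preset correlation. None of the 3 passed with an estimated correlation or in fry (adjusted p = 0.0638, 0.155 and 0.0638). Of 6 type-A response regulator genes, which are primary targets of cytokinin signalling, RR9 and RR4 fell and 0 rose, also adjusted over the list alone. RR4 changed by -0.81 (SE 0.13, limma adjusted p = 0.0294). The list had a camera adjusted p of 0.0158, adjusted p = 0.303 with an estimated correlation, 0.0874 without control array 2 and 0.0538 without IAA array 2. RR9 lost its call without control array 2 (adjusted p = 0.134) or either IAA array, and RR4 without any control or IAA array (adjusted p up to 0.254). Of 21 heat shock protein genes, HSP81-1 alone fell, at -0.72 (SE 0.13, limma adjusted p = 0.0487), also adjusted over the list alone, and kept its call in 4 of 17 other settings (camera adjusted p = 0.0105 for the list, and adjusted p = 0.227 with an estimated correlation). The 22 cyclin and histone genes held 0 calls, also adjusted over the list alone, with a median log2 change of -0.24 (camera adjusted p = 0.000588, and adjusted p = 0.25 with an estimated correlation).

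The other lists did not pass with IAA. Of 4 cytokinin dehydrogenase genes, CKX4 rose by 1.12 (SE 0.15, limma adjusted p = 0.00982), and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.825). Of 25 expansin genes, EXPB11 rose by 0.87 (SE 0.11, limma adjusted p = 0.00655), and adjusted over the list alone 5 rose and 3 fell (camera adjusted p = 0.623). Both genes lost their calls without control array 1 (adjusted p = 0.116 and 0.0821) or IAA array 1, and EXPB11 also without control array 2. The camera adjusted p was 0.817 for auxin carriers, 0.562 for type-B response regulators, 0.99 for cytokinin receptors with phosphotransfer proteins, 0.353 for ethylene-responsive and DREB factors and 0.136 for WRKY factors. It was 0.0776 for low-oxygen enzymes, 0.838 for dehydrins and LEA proteins, 0.217 for photosystem proteins, 0.0957 for root-preferential genes and 0.411 for ribosomal proteins. Each of these 10 lists held 0 calls, and beside PIN3A above, adjusted over the list alone 1 WRKY gene rose and 4 root-preferential genes fell. The low-oxygen enzymes passed downwards without rescaling between arrays (camera adjusted p = 0.00311), without control array 1 (0.0423), and without BAP array 1 or 2 (0.0104 and 0.00945), and had an adjusted p of 0.371 without IAA array 1. Root-preferential genes passed downwards without control array 1 (0.0397) or IAA array 2 (0.0247), and dehydrins and LEA proteins downwards without control array 1 (0.0234). WRKY factors passed upwards without control array 1 (0.0428) and photosystem proteins upwards without IAA array 1 (0.0482). The test and the median differed in sign for cytokinin dehydrogenases, expansins (there also the mean) and auxin carriers, and the test and the mean for cytokinin receptors with phosphotransfer proteins. The medians of expansins and ribosomal proteins, both close to 0, changed sign when each array was centred on its median.

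The second comparison asked which genes BAP changed against the control. BAP raised type-A response regulator genes and cytokinin dehydrogenase genes, whose products break cytokinins down. RR9 (LOC4349747) rose from an intensity of 272 ± 49.3 in the control to 1982 ± 104 with BAP (SD, n = 2 arrays each), RR6 (LOC4337372) from 609 ± 70.5 to 3213 ± 135, and CKX5 (LOC4327887) from 106 ± 2.89 to 453 ± 47.1. Transporter genes stood among the decreases: Lsi2 (LOC4331328), which encodes a silicon efflux transporter, went from 981 ± 138 to 302 ± 81.3, and NIP2-1 (LOC4330713), the silicon channel gene also called Lsi1, from 3526 ± 308 to 1889 ± 30.3. All these values compare arrays of different run days.

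In limma, 94 probe sets differed between BAP and control, of which 72 were higher and 22 lower with BAP. At least 2-fold changes made up 58 of the higher and 18 of the lower probe sets, and the calls covered 69 genes, 21 of them named. The count was 15 without control array 1, 18 without control array 2, 32 without BAP array 1 and 13 without BAP array 2. It was 14 with dim probe sets kept, 13 with a spread that did not follow intensity, 60 with each array centred on its median, 210 without rescaling and 0 in the plain two-group test (2353 at an unadjusted p under 0.05, against 2599 in limma).

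By the rule for named genes, all 17 genes in this paragraph had both BAP arrays on one side of both control arrays. On the log2 scale RR9 rose by 2.81 (SE 0.15, limma adjusted p = 0.000225), RR1 by 2.79 (SE 0.20, adjusted p = 0.000721) and RR4 by 2.41 (SE 0.13, adjusted p = 0.000225). RR6 rose by 2.37 (SE 0.12), RR2 by 2.10 (SE 0.15) and PSK2, which encodes a precursor of the peptide hormone phytosulfokine, by 1.92 (SE 0.13). The dehydrogenase genes CKX5, CKX4 and CKX3 rose by 1.94 (SE 0.22), 1.45 (SE 0.15) and 1.45 (SE 0.21), and CPD2, a brassinosteroid synthesis gene, by 1.29 (SE 0.14), with limma adjusted p between 0.00796 and 0.0297 for these 4 genes. Lsi2 changed by -1.67 (SE 0.20, limma adjusted p = 0.0126), the transcription factor gene bZIP37 by -1.56 (SE 0.11, adjusted p = 0.000721) and Nrat1 by -1.49 (SE 0.15, adjusted p = 0.00615). BHLH175, a helix-loop-helix protein gene also known as IBH1, changed by -1.45 (SE 0.20), VIT1.2 by -1.31 (SE 0.14), NIP2-1 by -0.89 (SE 0.10) and STT3-B by -0.70 (SE 0.10). A second probe set of BHLH175 read 0.29 (limma adjusted p = 0.699), so the fall of this gene rested on 1 of its probe sets. RR9, RR1, RR4, RR6, RR2, PSK2 and bZIP37 stayed past the threshold with each array left out, whereas the other 10 genes lost their calls without control array 1 and also without at least 1 further array, with adjusted p of 0.123 for Lsi2 and CPD2, 0.124 for NIP2-1, 0.105 for VIT1.2, 0.0842 for Nrat1 and 0.0845 for CKX4, and with adjusted p up to 0.314 for STT3-B without control array 2.

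Of 6 type-A response regulator genes, 5 rose and 0 fell with BAP, and adjusted over the list alone all 6 rose. The remaining one, RR5, read 2.12 (SE 0.35, limma adjusted p = 0.0587 over all probe sets). The list had a camera adjusted p of 6.87e-25, and adjusted p = 0.0979 with an estimated correlation. Of 4 cytokinin dehydrogenase genes, 3 rose, and adjusted over the list alone all 4 (camera adjusted p = 1.15e-09, and adjusted p = 0.26 with an estimated correlation). The fourth, CKX11, read 0.43 (SE 0.16, limma adjusted p = 0.519 over all probe sets). A second, dimmer probe set of CKX11 read -0.20 (limma adjusted p = 0.952), so its rise rested on 1 of its probe sets. Of 25 expansin genes, whose products loosen cell walls, EXPA2 rose by 1.27 (SE 0.12) and EXPB11 by 1.12 (SE 0.11), both with a limma adjusted p of 0.00531. Adjusted over the list alone, 6 expansin genes rose and 3 fell, with a camera adjusted p of 0.00652 and adjusted p = 0.26 with an estimated correlation. Both lost their calls without control array 2, EXPA2 had an adjusted p of 0.0636 without BAP array 2, and EXPB11 of 0.0699 without control array 1. The 15 TIFY genes held 0 calls, and 4 rose adjusted over the list alone (camera adjusted p = 0.01, adjusted p = 0.599 with an estimated correlation, and 0.0514 without BAP array 1). Their mean was 0.21, while their median of 0.03 fell just below 0 with each array centred on its median.

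Root-preferential genes and cyclins with histones ranked below other genes with BAP in camera at its preset correlation. Neither passed with an estimated correlation or in fry (adjusted p = 0.243 for both). Of 33 root-preferential genes, NIP2-1 fell and 0 rose, 13 had log2 values above 0, and adjusted over the list alone 6 fell (camera adjusted p = 0.0137, adjusted p = 0.462 with an estimated correlation, and 0.0661 without BAP array 1). The 22 cyclin and histone genes held 0 calls, also adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.0137, adjusted p = 0.547 with an estimated correlation, 0.139 without BAP array 2 and 0.0591 without rescaling between arrays). The 8 photosystem genes, markers of green tissue, held 0 calls, also adjusted over the list alone, and had a median of 0.00194 (camera adjusted p = 0.924).

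The auxin lists did not pass with BAP: the 25 Aux/IAA genes had a camera adjusted p of 0.656 and a median of 0.03, the 9 GH3 genes 0.834 and 0.02, the 16 auxin response factors 0.869 and 0.00382, and the 4 auxin carriers 0.559 and -0.15. The medians of GH3 genes and auxin response factors changed sign under another scaling. Adjusted over the list alone, 2 Aux/IAA genes and 1 GH3 gene rose. The camera adjusted p was 0.8 for ethylene synthesis, 0.656 for type-B response regulators and 0.834 for the LOG genes of cytokinin activation. For cytokinin receptors with phosphotransfer proteins it was 0.869, for ethylene-responsive and DREB factors 0.834 and for WRKY factors 0.834. It was 0.834 for glutathione S-transferases, 0.656 for heat shock proteins, 0.656 for low-oxygen enzymes, 0.0646 for dehydrins and LEA proteins, 0.869 for ribosomal proteins and 0.937 for clock genes. None of the lists in this paragraph held a call over all probe sets, although dehydrins and LEA proteins passed upwards in camera without rescaling (adjusted p = 2.28e-10). That list rested on the control arrays, with a camera adjusted p of 1.06e-05 without control array 2 and 0.771 without control array 1. Adjusted over the list alone, 1 ethylene synthesis gene, 1 cytokinin receptor or phosphotransfer gene and 2 dehydrin or LEA genes rose, while 1 type-B response regulator gene and 2 cytokinin receptor or phosphotransfer genes fell. The test and the median differed in sign for ethylene synthesis, WRKY, clock and cytokinin receptor genes.

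Lists with fewer than 3 measured genes were not tested as lists. They held only genes found by symbol or synonym, so family members known by locus number alone were not examined and the families were not assessed. Both listed peroxidase genes fell with IAA, as given above, and read -0.80 (PRX74, limma adjusted p = 0.0576) and -0.27 (PRX112) with BAP. SAUR39, the only small auxin-up RNA gene found by symbol, read -0.12 with IAA and -0.10 with BAP. LBD6, a LOB domain gene, read -0.26 and -0.14. The gibberellin oxidase gene GA20OX2 read 0.53 and 0.73, and GA20OX3 read 0.06 and -0.06. XRT5, of the xyloglucan endotransglucosylase family, read -0.16 and 0.33.

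The direct comparison of both hormones tested the difference between their effects, in which the control cancels. Type-A response regulators were higher, and some Aux/IAA and GH3 genes lower, with BAP than with IAA. RR9 was higher by 3.84 on the log2 scale (SE 0.15, limma adjusted p = 1.33e-05), RR4 by 3.22 (SE 0.13), RR6 by 2.65 (SE 0.12), RR1 by 2.59 (SE 0.20) and RR2 by 2.32 (SE 0.15). IAA20 differed by -3.59 (SE 0.14, limma adjusted p = 1.33e-05), IAA9 by -3.41 (SE 0.16), GH3-2 by -3.0 (SE 0.19), WOX6 by -2.92 (SE 0.22) and IAA26 by -2.88 (SE 0.24). All 10 kept their calls with each array left out, and by the rule for named genes had both BAP arrays on one side of both IAA arrays.

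In limma, 769 probe sets differed, of which 381 were higher and 388 lower with BAP than with IAA. Without rescaling between arrays the split was 625 to 349, and the median log2 difference over all tested probe sets was 0.0817. With each array centred on its median the split was 241 to 321. At least 2-fold differences numbered 403, and the calls covered 508 genes, 107 of them named. All 6 type-A response regulators and 2 of 4 cytokinin dehydrogenases were higher with BAP, whereas 12 of 25 Aux/IAA genes, 4 of 9 GH3 genes, 4 of 16 auxin response factors and 3 of 6 glutathione S-transferases were lower. Adjusted over the list alone these counts were 6, 3, 15, 4, 5 and 3. IAA7 was the Aux/IAA gene that was higher, by 0.74 (SE 0.15, limma adjusted p = 0.0433). Among the 8 LOG genes of cytokinin activation, LOGL6 was higher by 1.66 (SE 0.25) and LOGL3 lower, at -2.09 (SE 0.22). Adjusted over the list alone, 1 was higher and 6 lower. These lists and that of low-oxygen enzymes, which held 0 calls over all probe sets and 2 adjusted over the list alone, were the 8 past the threshold in camera, with adjusted p from 1.55e-17 to 0.0338. With an estimated correlation their adjusted p lay between 0.0815 and 0.346. In fry 9 lists passed. Auxin response factors and low-oxygen enzymes did not (fry adjusted p = 0.0698 and 0.0636). Auxin carriers, ethylene synthesis and expansins passed in fry but not in camera (fry adjusted p = 0.0122, 0.0473 and 0.0184). The count of probe sets was 310 without IAA array 1, 430 without IAA array 2, 322 without BAP array 1 and 348 without BAP array 2, and it was 234 with dim probe sets kept, 223 with a spread that did not follow intensity and 0 in the plain two-group test (2611 at an unadjusted p under 0.05, against 4356 in limma). Run day and hormone cannot be told apart in this comparison either.

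**Figure D2:**
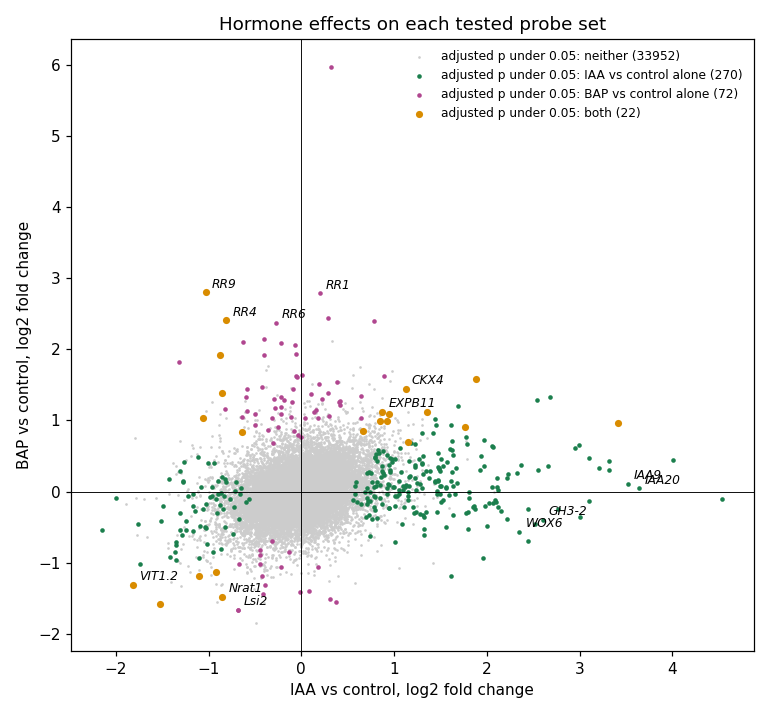
Log2 change with BAP against log2 change with IAA, both relative to the same control arrays, for each of the 34316 tested probe sets. Green, purple and orange points passed an adjusted p of 0.05 with IAA alone, BAP alone or both (22 probe sets), and grey points with neither; the orange points at upper left include RR9 and RR4.

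Both hormone comparisons used the same control arrays, which differed in fluidics module from all IAA and BAP arrays. The log2 changes correlated across probe sets at r = 0.314, below the mean of 0.501 from 100 simulations of unchanged groups against shared controls. The covariance was 0.0273 against a simulated 0.0234, a difference of 0.00389, or of 0.00501 when the shared part was taken from the spread of the control arrays alone. Changes had the same sign in 62.4% of probe sets, against 66.7% in the simulations. Leaving out control array 1 gave r = 0.445 and leaving out control array 2 gave r = 0.46, both below the simulated 0.667 for a single shared control. Of the probe sets called with both hormones, 11 were higher with both and 5 lower with both. In simulated unchanged groups, top-ranked lists as long as the called ones shared a mean of 18.1 (SD 3.86) and 5.57 (SD 1.98) probe sets. Noise of the shared controls ranked those lists, whereas the called lists also hold hormone effects, so this reference cannot decide the question. Simulated calls past the threshold, which were few, shared a mean of 0.11 and 0.1, and independent lists would share 0.455 and 0.0481. How much of either overlap came from the shared control arrays stays open. CKX4 and the expansin gene EXPB11 were among those higher with both, and VIT1.2 and Nrat1 among those lower with both, 4 genes chosen from the overlap after their values were seen. A further 6 were lower with IAA and higher with BAP, RR9 and RR4 among them. Independent lists would share 0.157, and shared controls lower that number. The opposite case had 0 probe sets, against 0.139 for independent lists. The control arrays were too few to be split with replicates on each side.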

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

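The tests of scaling and of run day were chosen after the result was seen, and the test over other genes raised by BAP before. With adjusted p under 0.05 in each comparison, 6 probe sets were lower with IAA and higher with BAP than in the control. BAP minus IAA was 3.84 on the log2 scale for RR9, 3.22 for RR4, 2.79 for LOC4339516, 2.25 for LOC4348669, 2.10 for LOC4350138 and 1.48 for LOC4341221. That limma called each difference adds no support, since the probe sets were chosen for opposite calls. The 4 genes known by locus number were chosen after their values were seen. With IAA, RR9 changed by -1.03 and RR4 by -0.81, and the locus-numbered genes by -0.88, -0.86, -1.06 and -0.64 in the order given. In the order RR9, RR4, LOC4339516, LOC4348669, LOC4350138, LOC4341221, their changes with BAP were 2.81, 2.41, 1.92, 1.39, 1.04 and 0.84.

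Scaling between arrays as the whole cause was argued against, since in the deposited values the 200 probe sets nearest in control intensity to each of the 6 had a median IAA change no lower than -0.126 (SE 0.0184). With any 1 array left out, RR9 stayed between -1.21 and -0.86 with IAA and RR4 between -0.91 and -0.71, but as they were chosen for their calls, a single deviating array stayed open. The run day stayed open for the rise with BAP, because 0 control arrays were run on the day of the BAP arrays. The fall with IAA lay within a single day but between fluidics modules, so module stayed open for it. A candidate biological explanation, that IAA lowers genes raised by cytokinin in general, could not be decided. The other 66 probe sets raised by BAP had a median IAA change of -0.024 (SE 0.0874), and 34 of them lay below 0. That median can lie too high, since the 6 were taken out and both comparisons share the control arrays. A narrower effect of auxin on response regulator genes may exist but was not tested on other samples, and, although the changes kept a similar size, the call of RR9 with IAA was lost without control array 2 or either IAA array, and that of RR4 without any control or IAA array (limma adjusted p up to 0.134 and 0.254), where fewer arrays were fitted.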

How the results depend on the processing

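All alternatives were chosen before the data were examined. Without the filter on dim probe sets the counts were 68 for IAA, 14 for BAP and 234 between hormones, where more probe sets were tested. Without a spread that follows intensity they were 92, 13 and 223, and a plain t-test gave 0 in each comparison. Without rescaling they were 502 for IAA and 210 for BAP, and with median centring 60 for BAP. A 2-fold minimum beside the adjusted p gave 403 between hormones, and a 2-fold minimum with an unadjusted p gave 212 for BAP. With an estimated correlation, where 3 residual degrees of freedom leave little power, 0 lists passed for IAA and 0 for BAP, and with fry 4 and 3. Where the construction of an alternative (more probe sets tested, fewer arrays, another threshold) does not account for the change, the cause was not tested. With 1 array left out, the lone array of a group was assumed to vary like the other groups. Counts then ranged from 85 to 287 for IAA, 13 to 92 for BAP and 310 to 591 between hormones, lists from 8 to 15 for IAA and 4 to 7 for BAP, and the correlation of both responses from 0.22 to 0.46. The replicate block gave 320, 95 and 756 probe sets and 11 and 7 lists (low-oxygen enzymes in place of ethylene synthesis for IAA, dehydrins and LEA proteins added for BAP), and ended 4 calls of named genes; the replicate numbers do not pair the samples (correlations of deviations across probe sets 0.0174, 0.0264 and -0.0595). The remaining alternatives kept counts within 1.5 times. Over 63 named results and their alternatives, 883 of 1070 values kept direction and side of the threshold. A further 187 kept the direction and lost the call, and 0 reversed. The 63 results were chosen because they passed the threshold, so the lack of reversals was largely set by that choice. Of them, 31 kept their call throughout. Changes near background are understated by the pseudocount.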

Other observations

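The test of root markers and the scaling test of the transporters were chosen after the result was seen, and the test of neighbouring genes before it; all genes and families in this part beyond the rule for named genes were chosen after their values were seen. Further named genes were raised by IAA in limma. DAO, which encodes an auxin oxidase, rose by 1.63 (SE 0.13, adjusted p = 0.00067), the protein kinase gene PID by 1.21 (SE 0.16) and the homeobox gene HOX1 by 1.30 (SE 0.18). CYP734A4, of a cytochrome P450 family that inactivates brassinosteroids, rose by 1.80 (SE 0.28), CYP87A3 by 1.81 (SE 0.19) and the transcription factor gene NAC3 by 1.66 (SE 0.10). WOX11, which acts in crown root formation, rose by 1.61 (SE 0.20), and the glutaredoxin genes GRXC3 and GRXC7 by 1.59 (SE 0.18) and 0.75 (SE 0.12). WOX10 did not pass with IAA, but WOX6, WOX11 and WOX10 all were lower with BAP than with IAA, at -2.92, -2.80 and -1.83.

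Families of genes sharing a name were compared with all other named genes by Fisher's exact test, adjusted over 204 families. For genes raised by IAA, 10 of 25 Aux/IAA, 4 of 9 GH3 and 3 of 6 OPR genes were called, with adjusted p of 1.73e-09, 0.00159 and 0.00942. For genes raised by BAP, 5 of 11 response regulator and 3 of 4 cytokinin dehydrogenase genes were called, at 3.25e-07 and 7.04e-05. Among genes lower with BAP than with IAA, which were run on different days, 3 of 5 WOX, 3 of 6 OPR, 3 of 7 NAC and 4 of 17 ARF genes were called beside Aux/IAA and GH3 genes (adjusted p = 0.0169, 0.0249, 0.0341 and 0.0451). The 17 ARF genes include one with the bare symbol ARF, which was not in the list of auxin response factors. A gene counted as called where any of its probe sets passed. NAC6, for example, read -0.75 on the called probe set and -0.19 on another (limma adjusted p = 0.824). For genes raised by IAA, WOX genes did not pass (2 of 5, adjusted p = 0.15). Members of a family are not independent, and the families were not set in advance.

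Genes without a name also changed. LOC4339041 rose by 4.54 with IAA (SE 0.19), from a mean intensity of 61.2 to 1782, and LOC4326578 by 4.0 (SE 0.26). A probe set with no gene in the tables used here read 0.85 and 8.13 in the control arrays, under the filter intensity of 9.94, and 962 and 1639 with BAP (limma adjusted p = 0.00028), so the size of its rise was not set.

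Genes raised by IAA lay beside each other on the chromosomes more often than random genes. Among 147 such genes, 10 pairs lay within 3 genes of each other, against a mean of 2.41 and a highest value of 9 in 2000 random sets. OPR5, OPR4 and OPR1 formed one such group, with increases of 1.93, 2.05 and 1.78, and GSTU6 lay near LOC4349204 and LOC4349212. The pairs were not independent. These groups, and that of LOC4330775, LOC4330777 and LOC4330779, each counted as more than a single pair, whereas the random sets drew genes independently. The number of pairs therefore overstates the number of clusters. A second probe set of OPR5 read 1.13 with IAA (limma adjusted p = 0.0581). The 10 pairs are consistent with copies of a cluster rising together, as a hypothesis. Signal shared between near-identical copies stays open as a technical explanation, since no probe sequences were used here.

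Lsi2, NIP2-1 and Nrat1, transporter genes for silicon and aluminium, were lower with BAP, at -1.67, -0.89 and -1.49. Whether a smaller share of root tissue in the BAP samples was the whole cause could not be decided. The other 32 genes of the root-preferential list had a median change of -0.0464 (SD 0.385). They were mostly CASP-like genes not examined for expression in the shoot, so their median need not follow the share of root tissue. At least a part of the fall may come from a smaller share of root tissue. With NIP2-1 included, the list ranked below other genes in camera (adjusted p = 0.0137, and 0.462 with an estimated correlation). Adjusted over the list alone, 6 of 33 fell and 0 rose. Scaling was argued against, as the 200 deposited probe sets nearest in control intensity to each of the 3 had a median change no lower than -0.048 (SE 0.0173). With IAA, on the run day of the control, Lsi2 read -0.68, NIP2-1 -0.44 and Nrat1 -0.85 (limma adjusted p = 0.216, 0.0957 and 0.0346). Run day, cytokinin, a smaller share of root tissue and a cause shared by both treatments, the control arrays and their fluidics modules included, therefore stay open.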
